A study of Homo sapiens with 12 samples.

How the data were processed

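Total RNA of 12 samples of differentiated Caco-2 cells was measured on 3' expression arrays, 1 array per sample. Per the labels' protocols, the cells were at passage 22, grown in 75 cm2 flasks in medium with 10% serum, and exposed for 24 h in 20 mL of medium with 1% of an insulin, transferrin and selenium supplement. Biotin-labelled cRNA was made from 250 ng of RNA, per the labels' protocols.

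The deposited values are log2 expression values per probe set, 1 column per array. RMA and Partek are named per the submitters' processing notes, and their versions and settings are not given in the sources used here. From the deposited log2 values themselves, the scale is log2, as the range shows, no centring per gene was applied, and higher values mean more signal. The column means were equal at 5.57. Whether the authors filtered or corrected the values in any further way is unknown. The column medians were 4.75, 4.72 and 4.74 for the medium arrays, 4.74, 4.73 and 4.74 at 2.5 µg/mL, 4.78, 4.76 and 4.76 at 25 µg/mL, and 4.79, 4.76 and 4.74 for the ion arrays. RMA usually sets the distributions of arrays equal, so a change in the total amount of mRNA per cell does not show in these values. The table gives no detection calls, so dim genes have no stated background.

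The table held 54675 probe sets, of which 62 were controls. In the platform annotation used here, 41097 had 1 gene symbol, 1801 had several and 11721 were not listed with a gene. Symbols were updated through the gene ID for 41043 of the first kind and 54 kept the older symbol. Each gene was represented by its 1-symbol probe set with the highest mean over all arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. No gene was named from a probe set with several symbols, so HSPA1A, whose probe sets also match HSPA1B, is not reported. Of 83 called named genes with several probe sets, 68 had all probe sets of one sign, and TXNRD1, TXNRD2, SQSTM1, CD44, COL3A1 and HFE were among those that did not. No coordinates are given, since the values carry no genome build. No 2 arrays held identical values.

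Genes were tested with limma 3.58.1 in R 4.3.3, with 1 linear model for the 4 groups of 3 arrays, 8 residual and 6.25 prior degrees of freedom, 6 two-sided contrasts and a moderated F test. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Errors given with log2 fold changes are standard errors from limma. The 33 gene lists, with 669 entries of which 607 were measured, and the rule for named genes were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with p-values adjusted over all lists and the 3 comparisons against medium together, and over the lists within each comparison between treated groups. Another 7 lists were chosen after seeing the data and appear only in the closing section. For the shared medium arrays, 100 simulations drew unchanged groups and a shared control from independent noise. The model and camera were tested on simulated data with 200 changed genes among the 19775.

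For each comparison against medium, the named genes were the 10 largest rises and 10 largest falls among called genes whose 3 treated arrays lay outside the range of the medium arrays. Added to these were up to 4 members of each list with the largest changes, the 5 largest in each direction between treated groups, and HMOX1, MT1X, MT2A, HSPA1A, DNAJB1, TXNRD1, GCLM and SLC30A1. Alternatives were quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, every probe set tested, intensity-trend, unmoderated and array-weight fits, fold thresholds, an adjusted p under 0.01, fits of only the groups compared, and leaving out each array. Scaling on the poly-A or hybridization control probe sets, and a fit with the replicate number as a block, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.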

Results

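Gene expression was measured in differentiated Caco-2 cells, an established human colon carcinoma line that takes on features of absorptive enterocytes when kept confluent. The cells were used 21 days after confluence and were exposed for 24 h. The 4 groups of 3 arrays each were cells in medium alone, cells given surfactant-coated silver nanoparticles at 2.5 µg/mL or at 25 µg/mL, and cells given silver nitrate, a source of silver ions, at 0.5 µg/mL. The series is about the molecular action of silver nanoparticles in this intestinal line, and the ion group allows the particle and ionic forms to be set side by side, although their doses differ. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. With 3 arrays per group, the number of arrays limits the precision. No group was given the surfactant alone, so its effect is not separated from that of silver in the nanoparticle groups.

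The 25 µg/mL arrays stood apart from all others. Across probe sets, arrays of 1 group correlated with r between 0.992 and 0.996, and medium and 2.5 µg/mL arrays with r between 0.993 and 0.996, whereas medium and 25 µg/mL arrays correlated with r between 0.978 and 0.981. These correlations are across probe sets, which are not independent replicates. Of the ion arrays, replicate 1 had the lowest correlation with its group, 0.992. Control probe sets outside the gene measurements also differed at 25 µg/mL. The 24 poly-A control probe sets were 0.61 higher on the log2 scale than on the medium arrays, the 18 hybridization control probe sets 0.43 higher and the 6 ribosomal RNA probe sets 0.64 higher, each on all 3 arrays (exact permutation test, two-sided p = 0.10, the smallest that 3 against 3 arrays can give). The poly-A means on 25 µg/mL replicates 1, 2 and 3 were 6.21, 5.56 and 6.31, and the highest medium value was 5.54. The poly-A rise, on which poly-A scaling rests, thus came mainly from replicates 1 and 3. Over all arrays the poly-A means lay between 4.95 and 6.31, near the median of all probe-set values, 4.75. They may therefore partly read background, which also limits poly-A scaling. The difference between 3' and 5' probe sets, a sign of RNA integrity, was 0.56 ± 0.14 for ACTB at 25 µg/mL and 0.63 ± 0.06 in medium (SD, n = 3). The highest ACTB values of all arrays were 0.96 on 2.5 µg/mL replicate 3 and 0.95 on ion replicate 3. For GAPDH these arrays had 0.16 and 0.18, within the medium range of 0.10 to 0.23.

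**Figure D1:**
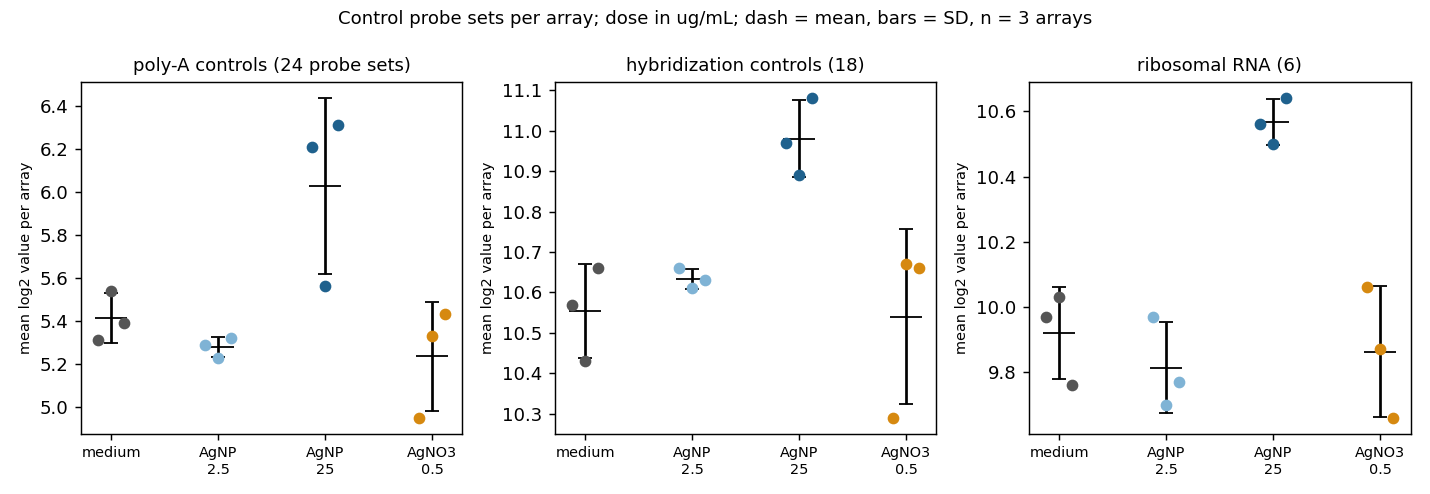
Mean log2 value of the poly-A control, hybridization control and ribosomal RNA probe sets on each array, by group, with silver doses in µg/mL on the horizontal axis; points are arrays, dashes are group means and bars are SD (n = 3). All 3 arrays at 25 µg/mL lay above the medium arrays in each panel, by mean log2 differences of 0.61, 0.43 and 0.64.

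Silver nanoparticles at 25 µg/mL changed a large part of the transcriptome, and metallothionein and heat shock genes were among the genes with the largest rises. HSPA6, an inducible HSP70 family chaperone, rose 122-fold (log2 fold change 6.93 ± 0.28 SE) from a mean log2 value of 5.32 in medium. The metallothionein MT1G rose 20.4-fold, and HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 17.2-fold. Among the largest falls were those of EPB41L3, a membrane skeleton adaptor (9.10-fold lower), the interferon-induced gene IFIT1 (8.52-fold lower) and the apolipoprotein gene APOC3 (8.15-fold lower). By limma, 6607 of 19775 genes changed at an adjusted p under 0.05, 2796 higher and 3811 lower, and 244 of them were at least 2-fold higher and 447 at least 2-fold lower. Scaling the arrays on the poly-A controls, chosen after seeing the data, moved the median of all genes by -0.61 and gave 179 higher and 14081 lower genes, and scaling on the hybridization controls moved it by -0.43 and gave 508 higher and 12835 lower. Directions below are therefore relative to the authors' normalization, under which the median of all genes was -0.011.

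Other genes with large rises were HSPA1L (23.6-fold), MT1E (18.4-fold), the natriuretic peptide gene NPPB (17.3-fold), MT1H (14.2-fold), MT1F (11.9-fold) and the small heat shock protein gene CRYAB (10.9-fold), all with adjusted p values of 6.8e-09 or lower in limma. Other large falls were of the acute-phase protein gene ORM1 (7.08-fold), the peptide hormone gene APELA (6.98-fold), the FGF co-receptor gene KLB (6.72-fold), the GABA receptor subunit gene GABRB1 (6.33-fold), the angiotensinogen gene AGT (6.2-fold), the amino acid transporter gene SLC38A4 (6.08-fold) and the aspartoacylase gene ASPA (5.74-fold). MT1M rose from a mean log2 value of 3.07 in medium, in percentile 1 of all genes, to 8.52, and no fold is given because the medium value has no stated background. HSPA1L lay at 4.52 in medium, and EPB41L3, IFIT1, SLC38A4 and ASPA at 4.51, 4.61, 4.45 and 4.18 at 25 µg/mL, below the medians of these arrays, so their folds are less certain. HSPA6 and CRYAB lay at 5.32 and 5.65 in medium, in percentiles 45 and 48 of all genes, so their folds also depend on the unstated background. Probe sets of the metallothionein copies and of the HSP70 copies share sequence, so the values of single copies are uncertain.

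Metallothioneins, small proteins that bind zinc, copper and silver, rose as a group at 25 µg/mL: 9 of 9 measured members were higher, also when adjusted over the list alone, with a median log2 fold change of 3.58. MT1X rose 10.3-fold and MT2A 7.75-fold. The camera test gave an adjusted p of 7.5e-13 for the list, and adjusted p = 0.14 with an estimated correlation. Of 25 zinc and copper transport genes, 6 were higher and 11 lower (adjusted over the list alone, 6 and 12), and the list did not pass the test (camera adjusted p = 0.34). Among them, the zinc exporter genes SLC30A2 and SLC30A1 rose 4.15-fold and 1.59-fold, the latter a call lost under poly-A (log2 fold change 0.05) and hybridization scaling (0.24), and the transporter gene SLC39A11 fell by 1.05 on the log2 scale.

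Heat shock genes rose in 16 of 20 measured cases and fell in 0 (18 and 0 adjusted over the list alone), with a median of 0.67 that became 0.06 under poly-A and 0.24 under hybridization scaling. DNAJB1, an HSP40 co-chaperone, rose 8.50-fold with a log2 fold change of 3.09 ± 0.08 (SE). The list passed camera (adjusted p = 1e-13) and did so with an estimated correlation as well (adjusted p = 0.016). Of 30 targets of the oxidative stress regulator NRF2, 19 were higher and 2 lower (19 and 3 adjusted over the list alone), with a median of 0.34 that turned to -0.28 under poly-A scaling and to -0.09 under hybridization scaling. The camera adjusted p was 2.8e-08, and adjusted p = 0.23 with an estimated correlation. Among these, SRXN1 rose with a log2 fold change of 2.58, AKR1B10 5.99-fold and GCLM, a subunit of the enzyme that limits glutathione synthesis, 4.82-fold. TXNRD1, thioredoxin reductase 1, rose 3.54-fold on the probe set used, while its other probe set had the opposite sign.

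All 13 immediate early genes, transcription factors and phosphatases that respond within minutes to growth signals and stress, were higher, also adjusted over the list alone (median 1.53, or 0.92 under poly-A scaling, camera adjusted p = 1.1e-13, adjusted p = 0.047 with an estimated correlation). FOSL1 rose 7.80-fold, FOS 6.03-fold and DUSP1 4.84-fold. Of 16 cytoskeleton and matrix genes, 10 were higher and 3 lower, adjusted over the list alone too (median 0.99, camera adjusted p = 0.00041, adjusted p = 0.14 with an estimated correlation). That median became 0.38 under poly-A and 0.56 under hybridization scaling, and 0.52 with the mean of a gene's probe sets. CCN2 rose 4.02-fold, ITGA2 3.57-fold and VIM 3.45-fold. Of 27 proteasome subunit genes, 13 were higher and 0 lower, adjusted over the list alone too, with a median of 0.21 that turned to -0.40 under poly-A and -0.21 under hybridization scaling (camera adjusted p = 0.00015, adjusted p = 0.65 with an estimated correlation). PSMD12 and PSMD1 rose by 0.91 and 0.63 on the log2 scale, calls that were lost under poly-A scaling (0.30 and 0.02) and for PSMD1 under hybridization scaling (0.21), and PSMC1 and PSMC4 had log2 fold changes of 0.60 and 0.57 that turned to -0.01 and -0.04 under poly-A scaling and lost their calls under hybridization scaling (0.17 and 0.15).

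Genes of lipid export, hepatocyte-type secretion and respiration fell at 25 µg/mL. Of 17 apolipoprotein and lipid export genes, 10 were lower and 0 higher, adjusted over the list alone too (median -0.52, camera adjusted p = 5.4e-05, adjusted p = 0.25 with an estimated correlation). Besides APOC3, the cholesterol exporter gene ABCA1 was 3.14-fold lower, and the triglyceride synthesis genes DGAT2 and DGAT1 were 2.90-fold and 2.65-fold lower. Of 14 hepatocyte-type secreted protein genes, 8 were lower and 0 higher, adjusted over the list alone too (median -0.63, camera adjusted p = 0.00086, adjusted p = 0.63 with an estimated correlation), among them ALB (5.56-fold) and RBP4 (2.17-fold). Of 29 nuclear-encoded genes of respiratory complex I, 20 were lower and 0 higher (22 and 0 adjusted over the list alone), with a median of -0.39, a camera adjusted p of 3.6e-06 and adjusted p = 0.65 with an estimated correlation. NDUFA7 was 1.93-fold lower and NDUFS7 1.66-fold lower. With the mean of a gene's probe sets the medians of the apolipoprotein and complex I lists were -0.29 and -0.21, and both kept their calls.

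Another 4 lists with lower members passed the preset camera test and were lost with an estimated correlation. In cholesterol biosynthesis 10 of 18 genes were lower and 0 higher, adjusted over the list alone too (median -0.38, camera adjusted p = 0.0021, adjusted p = 0.65 with an estimated correlation), with MSMO1 1.71-fold and MVD 1.68-fold lower. In PPAR signalling and fatty acid oxidation 8 of 15 were lower and 1 higher, adjusted over the list alone too (camera adjusted p = 0.022, adjusted p = 0.47 with an estimated correlation, 0.052 without dim genes and 0.054 under poly-A scaling), with ACSL1 1.86-fold lower. Among 19 junction genes 8 were lower and 0 higher (9 and 1 adjusted over the list alone), with a camera adjusted p of 0.023, adjusted p = 0.62 with an estimated correlation and 0.11 both without dim genes and under poly-A scaling, and the tight junction genes CGN and CLDN3 were 1.67-fold and 1.63-fold lower. Among 15 iron homeostasis genes 7 were lower and 2 higher, adjusted over the list alone too (camera adjusted p = 0.045, adjusted p = 0.65 with an estimated correlation), with the iron exporter gene SLC40A1 1.96-fold lower. The iron call was lost without medium replicate 2 (adjusted p = 0.072), without 25 µg/mL replicate 1 (0.064) or 3 (0.063), without dim genes (0.14), with quantile normalization (0.051), median centring (0.053) or array weights (0.053), and under poly-A (0.14) and hybridization scaling (0.098). The medians of the 7 lists with lower members lay between -1.24 and -0.79 under poly-A scaling and between -1.06 and -0.60 under hybridization scaling. All 13 lists that passed camera at 25 µg/mL also passed fry, with adjusted p values of 0.0074 or lower.

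The other lists did not pass camera as a whole but held changed members, in most of them in both directions. Of 26 enterocyte digestion and absorption genes, 1 was higher and 7 lower, adjusted over the list alone too, among them FABP1 (3.02-fold lower) and the intestinal alkaline phosphatase gene ALPI (2.61-fold lower). In the integrated stress response list 10 of 27 were higher and 3 lower (10 and 4 adjusted over the list alone), with ATF3 3.61-fold and SLC7A5 2.84-fold higher. In the NF-kB and inflammation list 7 of 19 were higher and 1 lower, adjusted over the list alone too, with the chemokine gene CXCL8 6.62-fold higher. These 2 lists passed camera, in the higher direction, under poly-A (adjusted p = 0.015 and 0.029) and hybridization scaling (0.0086 and 0.033). Their own medians were -0.57 and -0.46 under poly-A and -0.38 and -0.27 under hybridization scaling. Under both, these medians lay 0.05 and 0.16 above that of all genes. Scaling moves all genes of an array alike, so the gained calls do not show a shift relative to other genes. Among 22 selenoprotein genes 4 were higher and 7 lower, adjusted over the list alone too, with SELENOP 2.92-fold lower. In the drug metabolism list 5 of 23 were higher and 5 lower (6 and 6 adjusted over the list alone), with CYP1A1 3.11-fold higher and SULT2A1 2.65-fold lower. In hypoxia and glycolysis 7 of 19 were higher and 6 lower, adjusted over the list alone too, with PFKFB3 2.57-fold higher.

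Lists on growth and death also split. Of 24 proliferation genes, 8 were higher and 12 lower, with CCNE2 1.78-fold higher and AURKA 1.75-fold lower. Of 15 p53 and DNA damage genes, 4 were higher and 5 lower, with CDKN1A 2.01-fold higher. Of 18 apoptosis genes, 7 were higher and 4 lower, with BCL2L11 2.07-fold lower. Of 13 Wnt target genes, 3 were higher and 3 lower, with CCND1 1.86-fold higher. Of 12 fatty acid synthesis genes, 3 were higher and 3 lower, with ACSS2 2.15-fold lower. For these lists the counts adjusted over the list alone were the same. Medians and means differed in sign for the p53 list (0.02 and -0.02, camera direction higher), fatty acid synthesis (0.05 and -0.09, higher), Wnt targets (-0.05 and 0.05, higher), enteroendocrine genes (-0.04 and 0.17, higher) and fibroblast markers (0.09 and -0.18, lower). In the lysosome and autophagy list 7 of 22 were higher and 6 lower (8 and 8 adjusted over the list alone), with GLA 2.43-fold higher and WIPI1 2.42-fold lower. Of 20 endocytosis genes, 2 were higher and 5 lower (3 and 6 adjusted over the list alone), and of 22 ER chaperone genes, 3 were higher and 5 lower, adjusted over the list alone too, with CRELD2 1.86-fold higher. Under poly-A scaling the calls of CCNE2, CDKN1A, CCND1 and CRELD2 were lost, with log2 fold changes of 0.22, 0.39, 0.28 and 0.28.

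Lists of markers of other intestinal and non-epithelial cell types did not pass camera either. Of 18 mucin and goblet cell genes, 1 was higher and 3 lower (1 and 2 adjusted over the list alone), with TFF1 2.37-fold higher and MUC13 2.06-fold lower. Of 13 enteroendocrine genes, CCK was 6.59-fold higher and 0 were lower, adjusted over the list alone too. Of 10 stem cell markers, 2 were higher and 2 lower (4 and 2 adjusted over the list alone), and PROM1 fell by 0.58 on the log2 scale. Of 9 fibroblast markers, 2 were higher and 2 lower, with COL3A1 3.60-fold lower, and of 8 leukocyte markers, 1 was higher and 2 lower, with LYZ 2.48-fold lower, adjusted over the list alone too in both.

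**Figure D2:**
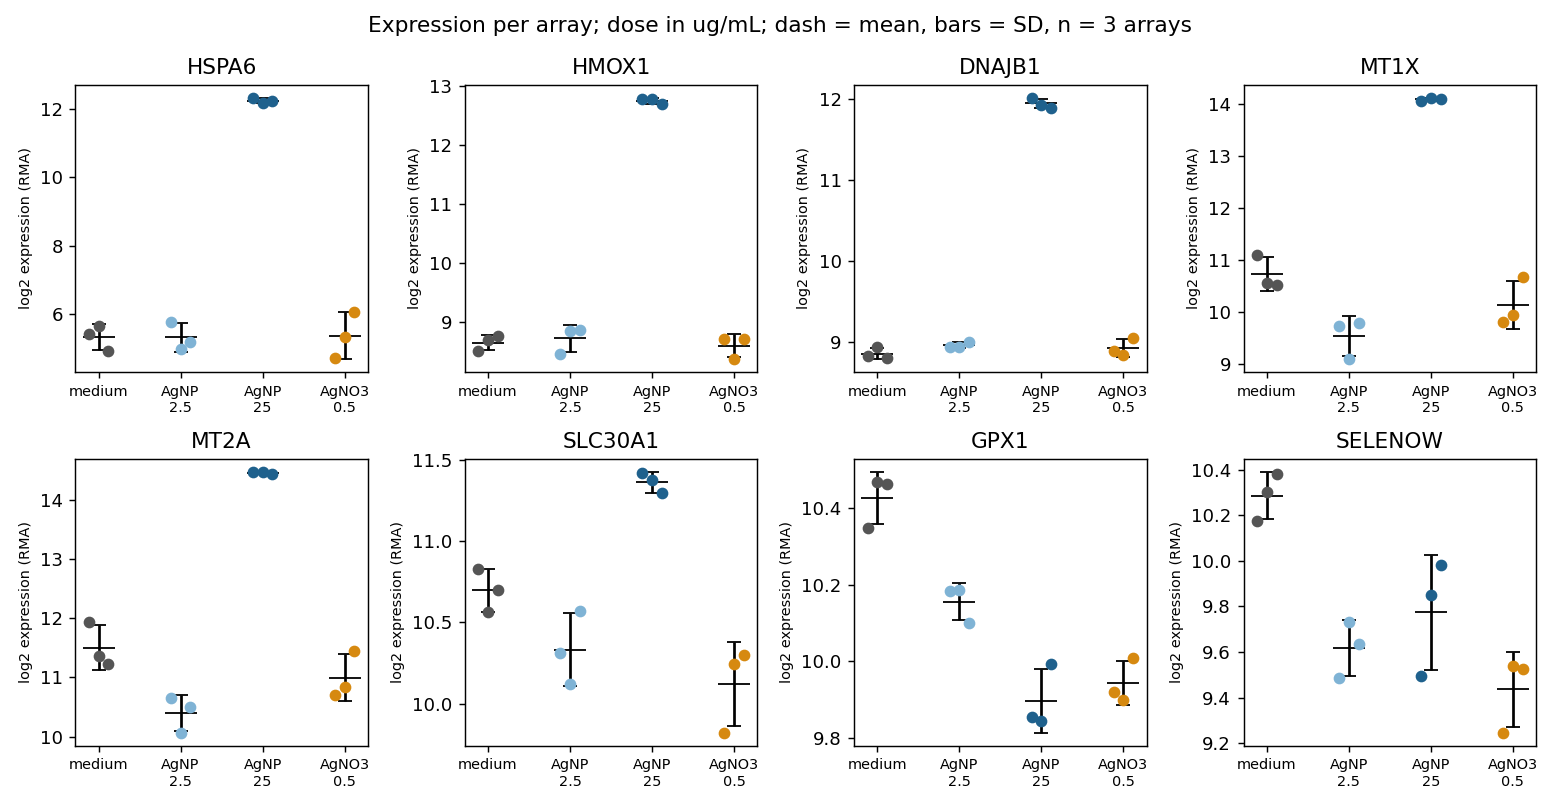
Log2 expression of 8 genes on each of the 12 arrays, by group, with silver doses in µg/mL on the horizontal axis; points are arrays, dashes are group means and bars are SD (n = 3). HSPA6, HMOX1, DNAJB1, MT1X, MT2A and SLC30A1 lay higher on all 3 arrays at 25 µg/mL than in medium, by log2 differences of 6.93, 4.10, 3.09, 3.37, 2.95 and 0.67.

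At 2.5 µg/mL 6 of 9 metallothionein genes lay below medium, the opposite of the higher dose, but no single gene passed the test over all genes. MT1X had a log2 fold change of -1.19 ± 0.22 (SE) and MT2A of -1.10 ± 0.20, each with an adjusted p of 0.34 in limma. HMOX1, DNAJB1 and GCLM, all raised at 25 µg/mL, had log2 fold changes of 0.07, 0.10 and -0.13, and TXNRD1 and SLC30A1 had -0.21 and -0.36. By limma, 0 of 19775 genes changed at an adjusted p under 0.05, 900 had an unadjusted p under 0.05 where 989 were expected by chance, and the intensity-trend, unmoderated and array-weight fits also called 0. In simulations with 200 changed genes among the 19775 and independent noise, 73.4% of genes changed 1.5-fold and 95.5% of genes changed 2-fold were recovered. The adjusted threshold is stricter when fewer genes change, so these shares do not give the recovery for a response of few genes. MT1X and MT2A, both past 2-fold here, were not called.

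Of the 9 metallothioneins at 2.5 µg/mL, 0 passed over all genes and 6 were lower adjusted over the list alone, with a median of -0.79. The list had a camera adjusted p of 1.8e-11, adjusted p = 0.16 with an estimated correlation, and a fry adjusted p of 0.031. Scaling on the hybridization controls, chosen after seeing the data, called 8 genes lower, among them MT1X (-1.27, adjusted p = 9.7e-05) and MT2A (-1.18, adjusted p = 0.00017), the lowest values over all alternatives, whose highest was 1 for both. Poly-A scaling, which moved the median of all genes by 0.13, called 0.

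Small shifts of other lists passed the preset camera test at 2.5 µg/mL and were lost with an estimated correlation, none of these 9 lists passed fry (adjusted p between 0.082 and 0.65), and in each of them 0 members passed over all genes. The integrated stress response list lay higher, with 26 of 27 members above 0 (median 0.12, adjusted p = 3.6e-06, adjusted p = 0.65 with an estimated correlation). Cholesterol biosynthesis lay higher in 18 of 18 members (median 0.12, adjusted p = 2e-05, adjusted p = 0.61 with an estimated correlation), led by LSS at 0.32. Wnt targets had a median of 0.11 (adjusted p = 0.017, adjusted p = 0.65 with an estimated correlation) and 2 higher members adjusted over the list alone. Lower medians were found for the proteasome (-0.09, adjusted p = 0.00015, adjusted p = 0.65 with an estimated correlation), NRF2 targets (-0.08, adjusted p = 0.00033, adjusted p = 0.47 with an estimated correlation) and complex I (-0.09, adjusted p = 0.00049, adjusted p = 0.78 with an estimated correlation). The same held for proliferation (-0.08, adjusted p = 0.0020, adjusted p = 0.79 with an estimated correlation), selenoproteins (-0.04, adjusted p = 0.0026, adjusted p = 0.47 with an estimated correlation) and heat shock genes (-0.09, adjusted p = 0.0077, adjusted p = 0.34 with an estimated correlation). Under poly-A scaling the medians of all lower lists named here changed sign, to values between 0.04 and 0.10, and those of the 3 higher lists were 0.25 each. Under hybridization scaling the lower lists had medians between -0.18 and -0.12, and the integrated stress response, cholesterol and Wnt lists 0.04, 0.04 and 0.03. Without 2.5 µg/mL replicate 3 the calls of the integrated stress response (median 0.03, adjusted p = 0.30), proteasome (-0.04, 0.29), complex I (-0.01, 0.69), proliferation (-0.02, 0.45) and heat shock (-0.04, 0.067) lists were lost. That array had the largest ACTB difference between 3' and 5' probe sets, 0.96, and whether RNA integrity bears on these calls was not tested. Without 2.5 µg/mL replicate 2 the integrated stress response and proliferation lists kept their calls with medians of 0.26 and -0.18. The heat shock call was also lost without medium replicate 2 (median -0.07, adjusted p = 0.072) and kept with array weights at a median of -0.05. The call of proliferation was also lost without medium replicate 3 (-0.04, 0.36) or 2.5 µg/mL replicate 1 (-0.05, 0.20). That of Wnt targets was lost without medium replicate 1 (0.07, 0.18) or 3 (0.06, 0.20), without 2.5 µg/mL replicate 2 (0.06, 0.30), without dim genes (0.11, 0.066) and with the mean of probe sets (0.03, 0.14), and it was kept without medium replicate 2 at a median of 0.21. The selenoprotein call was kept whichever array was left out, with medians of -0.08 without medium replicate 1, -0.07 without medium replicate 3 or 2.5 µg/mL replicate 2, and -0.02 without medium replicate 2 or 2.5 µg/mL replicate 3. Adjusted over the list alone, 2 selenoproteins were lower and 0 members of the other lists named here, Wnt targets apart, had changed. The remaining 23 lists did not pass camera. Of these, zinc and copper transport passed as lower without medium replicate 1 (adjusted p = 0.027) and under 4 other settings, hepatocyte-type proteins without medium replicate 1 (0.0094) or 2.5 µg/mL replicate 2 (0.037) and under poly-A scaling (0.046), PPAR signalling as higher without 2.5 µg/mL replicate 3 (0.016) and drug metabolism as higher without medium replicate 2 (0.033).

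With silver ions at 0.5 µg/mL several selenoprotein genes lay below medium, without passing the test over all genes. SELENOW had the lowest log2 fold change of all genes, -0.85 ± 0.13 (SE, adjusted p = 0.15 in limma), and GPX1, glutathione peroxidase 1, had -0.48 ± 0.08 (adjusted p = 0.26). The zinc exporter gene SLC30A1 had -0.58 ± 0.13, MT1X -0.59 and MT2A -0.51, while HMOX1, DNAJB1, GCLM and TXNRD1 had -0.06, 0.07, 0.10 and -0.25. By limma, 0 of 19775 genes changed at an adjusted p under 0.05, 1233 had an unadjusted p under 0.05 where 989 were expected by chance, the unmoderated and array-weight fits called 0, and the intensity-trend fit called 2, SELENOW (adjusted p = 0.0034) and GPX1 (adjusted p = 0.0045), both lower. Over all alternatives the adjusted p reached 1 for both.

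Of the 22 selenoproteins, 5 were lower and 0 higher adjusted over the list alone, and 0 passed over all genes. The list had a camera adjusted p of 3e-04, adjusted p = 0.32 with an estimated correlation, and a fry adjusted p of 0.024, and its median of -0.07 turned to 0.11 under poly-A scaling, which moved the median of all genes by 0.18. Its call was kept at a median of -0.04 with quantile normalization and of -0.11 without ion replicate 3. Zinc and copper transport genes had a median of -0.08, which turned to 0.09 under poly-A scaling, with 1 member lower adjusted over the list alone (camera adjusted p = 0.0077, adjusted p = 0.47 with an estimated correlation, fry adjusted p = 0.18). The metallothioneins had a median of -0.26, or -0.09 under poly-A scaling, with 0 members past the list-alone threshold (camera adjusted p = 0.049, adjusted p = 0.71 with an estimated correlation, fry adjusted p = 0.58). The call of zinc and copper transport was lost without ion replicate 1 (median -0.01, adjusted p = 0.16), with quantile normalization (-0.05, 0.051) and with the mean of probe sets (-0.04, 0.17), and kept without medium replicate 2 (-0.05, 0.033) and with array weights (-0.04, 0.040). That of the metallothioneins was lost without medium replicate 1 (-0.10, 0.69) or ion replicate 1 (-0.12, 0.096) or 2 (-0.20, 0.43), with quantile normalization (-0.24, 0.059), median centring (-0.29, 0.076), the mean of probe sets (-0.24, 0.095) and array weights (-0.17, 0.13), and kept without ion replicate 3 (-0.48, 0.0014). The other 30 lists did not pass camera. With 1 array left out some did: hepatocyte-type proteins (adjusted p = 0.018), apolipoproteins (0.020) and proliferation (0.038) without medium replicate 1, Wnt targets (0.012) without medium replicate 2, and cholesterol biosynthesis (0.034) without ion replicate 1. Without ion replicate 2 apolipoproteins (0.030) and proliferation (0.020) passed, and without ion replicate 3 junctions (0.015), NRF2 targets (0.016) and hepatocyte-type proteins (0.046). With the mean of probe sets junctions (0.0017) and NRF2 targets (0.031) passed, and apolipoproteins did with quantile normalization (0.046), the intensity trend (0.028) and hybridization scaling (0.050, just under the threshold).

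**Figure D3:**
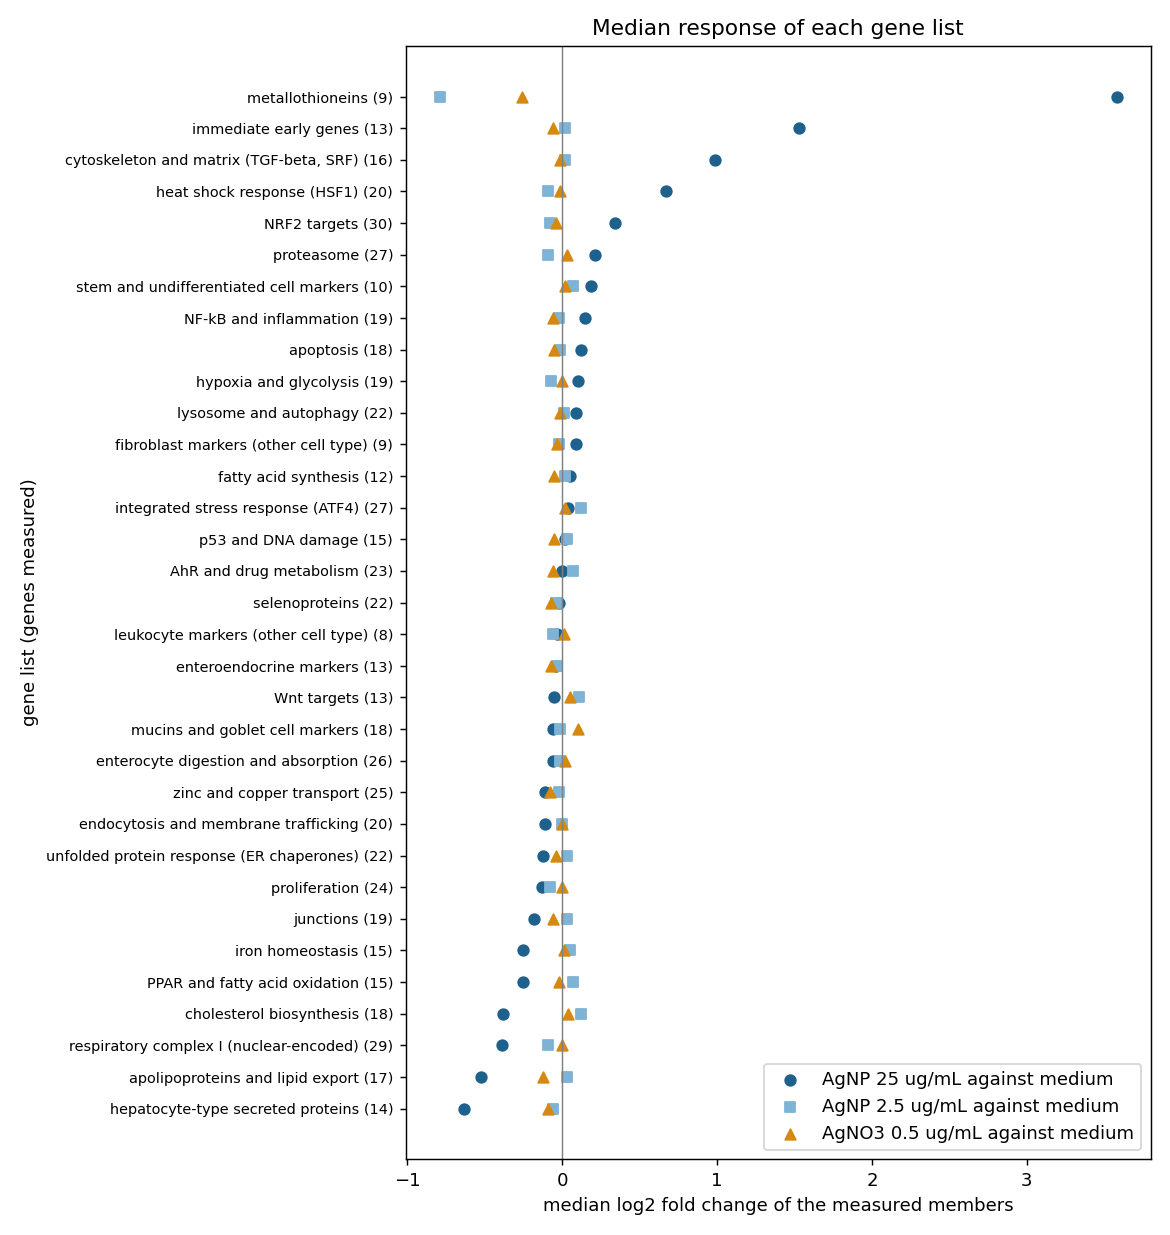
Median log2 fold change against medium (horizontal axis) of each gene list, with the number of measured genes in parentheses; circles are nanoparticles at 25 µg/mL, squares nanoparticles at 2.5 µg/mL and triangles ions at 0.5 µg/mL. The metallothionein medians were 3.58, -0.79 and -0.26, and the medians of the other lists at 2.5 µg/mL and with ions lay close to 0.

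Set against the other silver groups, heat shock and metallothionein genes were among those with the largest positive differences on the 25 µg/mL arrays. MT1M, at 3.08 with 2.5 µg/mL and 3.21 with ions, was also higher and is given no fold. Between the 2 nanoparticle doses, HSPA6 was 123-fold, MT1G 34.8-fold, MT1E 31.9-fold and MT1H 25.7-fold higher at 25 µg/mL, and EPB41L3 9.89-fold, APOC3 8.64-fold, ASPA 7.52-fold, APELA 7.18-fold and ORM1 7.17-fold lower. Against ions, HSPA6 was 119-fold, MT1G 24.0-fold, MT1E 23.7-fold and HSPA1L 19.7-fold higher, and EPB41L3 8.52-fold, APOC3 7.50-fold, IFIT1 6.96-fold, ORM1 6.56-fold and APELA 6.23-fold lower. By limma, 6717 genes differed between the doses (2705 higher at 25 µg/mL, 4012 lower) and 6378 between 25 µg/mL and ions (2702 higher, 3676 lower). Poly-A scaling, which moved the median of all genes by -0.75 and -0.79, gave 134 higher and 16869 lower genes between the doses and 141 and 17368 against ions, and hybridization scaling, which moved it by -0.34 and -0.44, gave 569 and 9067, and 498 and 13817. Genes called in the same direction against medium numbered 5725 and 5454 of these, and 5108 were called in all 3 comparisons. Heat shock genes passed camera with an estimated correlation in both (adjusted p = 0.0036 against 2.5 µg/mL and 0.0031 against ions), as did immediate early genes (0.020 and 0.011).

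Between 2.5 µg/mL nanoparticles and ions, the metallothioneins had a median log2 difference of -0.54, lower with nanoparticles, and 5 of 9 were lower adjusted over the list alone. The list had a camera adjusted p of 2.5e-05, adjusted p = 0.46 with an estimated correlation, and a fry adjusted p of 0.28. By limma, 0 genes differed at an adjusted p under 0.05, 1735 had an unadjusted p under 0.05 where 989 were expected by chance, the unmoderated and array-weight fits called 0, and the intensity-trend fit called 1, CEACAM6 (-0.47), named here after its value was seen. The doses of silver differ between these groups, and only the nanoparticles carried a surfactant, so form, dose and surfactant are not separated.

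Over all 4 groups, the moderated F test of limma called 6287 of 19775 genes, of which 5811 were also called at 25 µg/mL against medium. Only 46 of them were called in no comparison that involved the 25 µg/mL arrays. The responses against medium share the same 3 medium arrays, so their log2 fold changes correlate by chance: unchanged groups simulated against a shared control, itself simulated, gave r = 0.50 across genes and a covariance of 0.00655. This r holds for 2 unchanged groups, so it is no reference for pairs with 25 µg/mL, and covariances were compared instead. The observed r and covariance were 0.26 and 0.0144 for 25 µg/mL and ions, 0.06 and 0.00333 for the 2 nanoparticle doses, and 0.33 and 0.00517 for 2.5 µg/mL and ions, so the covariance lay above the simulated value for the pair of 25 µg/mL and ions and below it for the others. The simulated noise was independent between arrays, whereas same-numbered arrays shared some deviations (r up to 0.36). Covariances below the simulated value therefore carry no reading here. Genes are not independent replicates. At an unadjusted p under 0.05, 474 genes passed with the same sign at 25 µg/mL and with ions (209 higher, 265 lower, against 122 and 126 for independent lists), 304 at both doses (204 and 100, against 95.1 and 84.7) and 151 at 2.5 µg/mL and with ions (88 and 63, against 18.7 and 9.99). The simulated mean of 97.8, from 2 unchanged groups, applies to the last pair only, since 8109 genes passed at 25 µg/mL. For the pairs with 25 µg/mL, the counts for independent lists leave out the shared medium arrays, so the size of any excess is unknown. The 3 medium arrays are too few to split, so part of any excess may come from them.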

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

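The tests of explanations given here, and their bounds, were chosen after the results were seen, and some bounds were revised with the values known: those for short abundant transcripts more than once, at last to add the ribosomal proteins and to set both lists against the size of the pattern, and that for the metallothioneins once, to add the separation of array means. The tests over other splits of the arrays, given under the other observations, were planned.

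Of 9 metallothionein genes, 6 lay on opposite sides of medium at the 2 nanoparticle doses: every 25 µg/mL array lay above and every 2.5 µg/mL array below the medium arrays. This held for MT1E, MT1F, MT1G, MT1H, MT1X and MT2A, with log2 differences between the doses of 5, 4.44, 5.12, 4.69, 4.56 and 4.05, each past the threshold in the direct comparison by limma. Over all genes, 160 of 3914 with every 25 µg/mL array above medium had every 2.5 µg/mL array below it (4.1%), and 328 of 5117 with every 25 µg/mL array below medium had every 2.5 µg/mL array above it (6.4%). Chance gives 5% for 3 against 3 arrays, and 1.2% for genes unchanged in all 3 groups, since the medium arrays are shared.

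For the lower metallothioneins at 2.5 µg/mL, 1 deviating array is argued against, since the list median stayed at -0.58 or lower whichever of the 6 arrays was left out, the weakest value being without medium replicate 1. Medium arrays that were high by chance are only weakly argued against by the comparison with the ion arrays, where no medium array enters: the median difference was -0.54 and every 2.5 µg/mL array had a lower list mean than every ion array, although the fry p of 0.030 became 0.28 when adjusted. The gap was small, from 7.38 on the highest 2.5 µg/mL array to 7.51 on the lowest ion arrays. Arrays at 2.5 µg/mL that were low by chance would give the same result and stay open. The 6 MT1 and MT2 probe sets behaved nearly as a single signal, with a mean residual correlation of 0.89 over the 9 arrays without 25 µg/mL, as shared probe sequence would give and as common regulation would too. The number of independent genes behind the pattern may therefore be small, and the dose of silver stays open as a biological explanation that was not tested separately.

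GPX1, SELENOW and SELENOH lay below every medium array on all 9 silver-treated arrays, with mean log2 fold changes over the 3 genes of -0.56 with ions, -0.37 at 2.5 µg/mL and -0.47 at 25 µg/mL. A general loss of short abundant transcripts as the whole cause is only weakly argued against for ions and at 2.5 µg/mL. With ions the complex I and cytoplasmic ribosomal protein transcripts had medians of -0.00073 and -0.0074. At 2.5 µg/mL they had -0.093 (-0.13 to -0.014 with 1 array left out) and 0.014 (0.0084 to 0.023), against -0.42 to -0.34 for the mean of the 3 genes. Transcript lengths were not used, and these lists were not matched to the 3 genes in length or level. The explanation stays open at 25 µg/mL, where complex I had a median of -0.39 and the ribosomal proteins, whose mean levels had a median of 13.82, near the top of the range, -0.18. Signals so near the top may show a loss less fully in any group. The argument for ions and 2.5 µg/mL therefore rests mainly on complex I, whose mean levels had a median of 10.44. Medium arrays that were high by chance may also account for the pattern and cannot be told apart from an effect of silver here: 101 genes had all 3 medium arrays above the other 9, where chance gives 89.9, and although 3 of 22 selenoproteins did, where chance gives 0.1 for independent genes, these 3 varied together (estimated correlation 0.58). These 3 genes were picked for the pattern, out of 22 selenoproteins, and an effect of silver on them stays open and untested.

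Control probe sets, which the gene comparisons do not use, were higher on every 25 µg/mL array than on every medium array: by 0.61 for the poly-A controls, 0.43 for the hybridization controls and 0.64 for the ribosomal RNA probe sets. The poly-A rise came mainly from 25 µg/mL replicates 1 and 3, with replicate 2 at 5.56 against a highest medium value of 5.54. Less labelled target from the cells, or the normalization, was not tested apart from these values. A lower share of messenger RNA in the labelled RNA predicts a larger rise of the poly-A controls, provided they were added before labelling. The poly-A rise beyond the hybridization controls was 0.19 (exact permutation test, two-sided p = 0.40), above medium on 2 of 3 arrays. This explanation therefore cannot be told apart from none with 3 arrays per group, also because the poly-A values lay near the median of all probe sets and may partly read background. No biological explanation was tested.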

How the results depend on the processing

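Scaling on the poly-A or hybridization controls and the replicate block were chosen after seeing the data; the other alternatives for counts of genes were planned. The labels give the arrays letters and pair none of them; with the replicate number, which only follows the order of deposit, as a replicate block, 6976, 7095 and 6792 genes were called at 25 µg/mL against medium, 2.5 µg/mL and ions, 6824 in the F test, 0 at 2.5 µg/mL against medium and against ions, and 1 with ions, SELENOW. Deviations of 5 of 12 arrays correlated best with their own number in each of the other 3 groups, a hint from the data and not from the design. The letters run from B to P and skip H, J and M, and why is not stated. Arrays of the same number therefore need not be matching replicates.

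Testing every probe set gave 14162 calls at 25 µg/mL against medium, 14181 against 2.5 µg/mL, 13533 against ions and 13369 in the F test, since more features were tested. Requiring at least 1.5-fold gave 2523, 2655, 2370 and 3094, and at least 2-fold 691, 733, 614 and 870. Poly-A scaling gave 14260, 17003, 17509 and 16331, and hybridization scaling 13343 and 14315 against medium and ions and 12408 in the F test, by their shift of all genes. For 25 µg/mL against medium the share of higher calls was 42.3%, 1.26% with poly-A and 3.81% with hybridization scaling; against 2.5 µg/mL 40.3% became 0.788% with poly-A scaling. Leaving out 1 array gave 5577 to 5888, 5862 to 6024, 5411 to 6145 and 5002 to 6390 calls. At 2.5 µg/mL hybridization scaling called 8 genes. For ions 1 gene, SELENOW, was called with the mean of probe sets and with hybridization scaling, 1 probe set when all were tested, and 2 genes in the intensity-trend fit, which called 1 between 2.5 µg/mL and ions; the cause was not tested.

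With dim genes left out, r was 0.05 for the 2 doses and 0.37 for 2.5 µg/mL and ions. Over genes called at least 1.5-fold at 25 µg/mL, a set chosen after seeing the data, r was 0.35 for 25 µg/mL and ions and 0.45 for 2.5 µg/mL and ions; the cause was not tested.

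The unmoderated fit has no camera test, so it gives no value for the lists. At 25 µg/mL, 125 of 139 called named genes kept their call under all alternatives other than the 2 control scalings and the replicate block, which was run for counts of genes only, as did 10 of 13 called lists; 4 of 10 did at 2.5 µg/mL, where 4 uncalled lists gained a call under some, and 1 of 3 with ions, where 7 did. Under poly-A scaling, signs turned for RELB (-0.04), CCL20 (-0.17), ELOVL6 (-0.01), CD44 (-0.06), PSMC1 (-0.01), PSMC4 (-0.04), COL1A2 (-0.27) and LCP1 (-0.39), and under hybridization scaling for COL1A2 (-0.09) and LCP1 (-0.20), by the shift of all genes. Another 18 and 11 named genes lost their call under poly-A and hybridization scaling.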

Other observations

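The lists in the next paragraph, their tests and the correlations in the last paragraph were chosen after the results were seen; the splits of the arrays were planned.

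Interferon-stimulated genes were lower at 25 µg/mL in 23 of 35 measured cases and higher in 0 (median -0.75, camera adjusted p = 5.7e-11, adjusted p = 0.037 with an estimated correlation). Besides IFIT1, IFIT2 was 4.19-fold, ISG15 3.62-fold and OAS1 2.96-fold lower. Ribosome biogenesis genes were higher in 25 of 27 cases and lower in 0 (median 0.73, adjusted p = 0.0083 with an estimated correlation), with RRP15 2.55-fold and NOP58 2.17-fold higher, while 17 of 39 cytoplasmic ribosomal protein genes were lower and 0 higher (median -0.18, adjusted p = 0.41 with an estimated correlation). Of 14 feedback regulators of ERK signalling, 13 were higher and 0 lower (median 0.95, adjusted p = 0.052 with an estimated correlation), with DUSP6 4.73-fold and ETV5 3.64-fold higher. Of 19 coagulation and protease inhibitor genes, 17 were lower and 0 higher (median -0.97, adjusted p = 0.037 with an estimated correlation), among them KNG1 (4.83-fold) and SERPINA10 (4.06-fold). Of 35 nuclear-encoded genes of respiratory complexes II to V, 25 were lower and 0 higher (median -0.35, adjusted p = 0.41 with an estimated correlation). Of the 3 selenoproteins sensitive to selenium supply, GPX1, SELENOW and SELENOH, 3 were lower at 25 µg/mL (median -0.51, camera adjusted p = 0.031, adjusted p = 0.39 with an estimated correlation). With ions their median was -0.48 (camera adjusted p = 2.4e-10, adjusted p = 0.020 with an estimated correlation) and at 2.5 µg/mL -0.27 (9.2e-07, and 0.037 with an estimated correlation), with 0 genes called over all genes in either group and 3 and 2 lower adjusted over the list alone. These lists were picked because members stood out in these arrays, so their counts are not independent evidence.

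Over 100 splits of the 12 arrays into 4 groups of 3, the real one included, 1 gave as many genes in the F test as the 6287 of the real groups, and the highest other split gave 0. This argues against a random assignment of these arrays to groups. None of the other splits kept the 25 µg/mL arrays together: 50 kept at most 1 and 49 at most 2 in a group. Each thus moved the large 25 µg/mL difference into the residual spread, which led to low counts. Nothing follows about the other groups or about separate cultures. For each comparison of 3 against 3 arrays there are only 10 splits, too few for a share under 0.05. The real counts were 6607 at 25 µg/mL against medium, 6717 against 2.5 µg/mL and 6378 against ions, each reached by 1 of the 10 splits, with a highest other count of 0. For 2.5 µg/mL and ions against medium, and for 2.5 µg/mL against ions, the real count was 0, reached by all 10 splits, and the highest other counts were 0, 1 and 1.

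On the second principal component of the 12 arrays, which held 9.2% of the variance, replicate 1 lay highest and replicate 2 lowest in each of the 4 groups. Ion replicate 1 lay far from the rest on it, at 27.9, and the next highest array was medium replicate 1 at 7.51. The component thus largely marks that ion array. Replicate numbers follow the order of deposit, and the labels name no batch. Across genes, the deviations of same-numbered arrays from their group means correlated with r between 0.07 and 0.36 for number 1, 0.10 and 0.25 for number 2, and -0.07 and 0.10 for number 3, with 6 pairs of arrays each.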
